A study of Mus musculus with 18 samples.

How the data were processed

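Per the labels, 18 samples of T cells were sorted from female Foxp3 reporter mice on the C57BL/6 background that had received 50000 B16F10 melanoma cells under the skin. Tumours and spleens were taken when tumours measured about 10 mm across, the isolated cells were pooled before sorting, and Treg, Tconv and CD8 cells were gated free of CD11b. Per the labels, 2.5 ng of RNA was amplified and labelled with biotin for arrays of the Illumina mouse platform. The replicate letter of a sample goes with its BeadChip per the file headers, so that each BeadChip held 1 array of each of the 6 groups. Per the same headers each group had the same position letter on every BeadChip, so that group and position cannot be told apart. Whether replicates came from separate animals is not given in the sources used here, and p-values measure the spread between these samples.

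The deposited signal table holds the mean bead intensity of each of 46237 probes on each array, with neither background correction nor normalization between arrays per the file headers, and a detection p-value for each, also per the file headers. The software behind these values is not given in the sources used here. From the values, the deposited detection p-value is a 1-sided test of a probe's beads against 1 background level for each array. The authors also deposited a value table in intensity units, which from its values is linear and normalized between arrays, by a method not given in the sources used here, with column medians of 83.5 to 85.9 and a rank correlation of at least 0.999 with the signals of the same sample. Whether it was centred is not given in the sources used here. Median signals ran from 79 to 88.1, with a background of 77.0 to 86.0, and 38.0 to 45.2 percent of probes were detected at p under 0.05.

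Signals were corrected with neqc of limma 3.58.1 in R 4.3.3, which infers the background from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Since those p-values come from beads, the inferred spread of the background (2.08 to 2.49) is that of bead means and not of negative control probes. The offset compresses folds of dim genes, and the floor lies near 4. Of the probes, 35784 had 1 gene name in the platform table, 0 had several and 10453 had none; 28620 names were updated through the Entrez number, 2637 through an accession and 4527 were kept as given. A probe was kept if detected at p under 0.05 on at least 3 of the 18 arrays (27474 probes, 22409 with a name), and each gene was given by its probe with the highest mean, which left 14581 genes. The named genes that pass this filter on another probe as well are compared in the report.

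All arrays entered 1 linear model of limma with a mean for each group, lmFit and eBayes, with 12 residual degrees of freedom. The comparisons were 3 of tumour against spleen, 4 between cell types within a tissue and 2 differences of differences, each adjusted over the genes tested by Benjamini-Hochberg with a threshold of 0.05. A total of 23 gene lists, 15 of T cell programmes and 8 of other cell types, were tested with camera of limma at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, adjusted over all lists and comparisons, 207 tests. Of these 86 passed, 43 of them also with an estimated correlation and 72 with fry. Group sizes, comparisons, lists, thresholds, alternatives and the rule for named genes were set before the data were examined. The rule names the sorting markers and Thy1, the 8 largest rises and the 8 largest falls of each comparison among genes past the threshold with 1 direction on all 3 BeadChips, and the 6 members of each list with the smallest p in each comparison.

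Arrays of the same BeadChip were checked for a shared deviation: residuals of arrays with the same number correlated by 0.0424 on average, with 5 of 45 pairs above 0.1, and those of different numbers by -0.0208. Residuals cancel within each group, which ties the second value to the first. The model without the number was set before, with the number as an alternative, the replicate block. An average over genes can hide a BeadChip difference of single genes, such as Lyz1, given in the report. Arrays of 1 group correlated across genes, which are not independent replicates, by 0.913 to 0.972. The mean signal of the tumour Treg arrays was 147, against 127 to 131 in the other groups. These arrays also shared 1 position on every BeadChip, and whether the position contributes was not tested.

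The precision was tested on simulated data for the 14581 genes, with 50 genes raised or lowered by each size and 14381 left unchanged. For tumour against spleen Treg, 48 of the 50 genes raised by 2 on the log2 scale were called, 24 of those raised by 1, 26 of those lowered by 1 and 45 of those lowered by 2, with 13 unchanged genes called. For the difference of differences against Tconv the calls were 32, 13, 19 and 35, with 9 unchanged genes. A list of 20 genes raised by 1 was found, and 0 of 20 other lists were. Genes were simulated as independent of each other, so that false calls of lists whose genes vary together could not appear.

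Alternatives were other background corrections (none, or normexp with an offset of 50), median scaling, the authors' values, no filter or a filter at a detection p under 0.01, the mean of all probes or every probe, the replicate number as a block or a random effect, array weights, eBayes with trend and robust, only the groups of the comparison, a change of at least 1 on the log2 scale, and the fits without each replicate number or each array. The probe with the largest variance was added as an alternative after the data were seen. Probes without a gene name were left out of the comparisons. Tables were handled with pandas 2.3.3 and numpy 2.4.6 and figures drawn with matplotlib 3.10.9 in Python 3.11.15.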

Results

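Gene expression was measured on 18 Illumina BeadChip arrays of T cells sorted from female C57BL/6 mice with subcutaneous B16F10 melanoma, a transplantable mouse tumour line of the pigment cell lineage. Regulatory T cells (Treg), conventional CD4+ T cells without Foxp3 (Tconv) and CD8+ T cells were each taken from tumour and from spleen, which gave 6 groups of 3 replicates. Each of the 3 BeadChips carried 1 array of every group, with each group always at the same position, so that every comparison is also one between positions. The number of arrays, 3 in each group, limits the precision of every difference. Of the genes with a name, 14581 had a probe detected on at least 3 arrays. Differences are in log2 intensity ± SE, with n = 3 arrays in each group, and p-values are adjusted over the genes tested. Where no probe of a gene was detected on any array of 1 group, the difference is given as at least N-fold. That bound is the mean of the brighter group over a mean in the dimmer group that takes, on each array, the higher of the lowest detected signal and the gene's own value. Differences of differences carry no such bound, also where a gene was not detected in a group. Each gene is given by its brightest detected probe, and a dimmer detected probe that did not pass is named beside it.

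The genes used for sorting were examined first. Foxp3, the transcription factor that defines Treg, had 4 probes that did not behave alike. On 1 probe the 6 Treg arrays lay between 8.24 and 9.32 and the 12 other arrays between 4.07 and 4.41 on the log2 scale. It was detected on 1 of 3 Tconv arrays in each tissue. As a lower bound, with each undetected value raised to the lowest detected signal of its array, Treg exceeded Tconv on this probe at least 31.4-fold in the tumour and at least 17-fold in the spleen. The brightest Foxp3 probe, which the rule for 1 probe per gene selects, was detected on all 12 of the other arrays and gave -0.02 ± 0.28 in the tumour and 0.17 ± 0.28 in the spleen, neither past the test. The other 2 probes did not separate Treg either. Cd4 was lower in CD8 cells than in Tconv, by -4.48 ± 0.17 in the tumour and -4.34 ± 0.17 in the spleen, and Cd8b1, a chain of the CD8 coreceptor, was higher by 4.89 ± 0.43 and 4.53 ± 0.43. A dimmer Cd8b1 probe gave -1.34 and -0.75, neither past the test. Il2ra (CD25) and Itgam (CD11b) lay near the background in every group, with means of 4.41 and 4.23 in tumour Treg, and neither probe of Cd8a passed the detection filter. Thy1, which the reporter strain carries in a second form, did not differ between groups past the test, with 0.14 ± 0.15 for Treg against Tconv in the tumour.

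**Figure D1:**
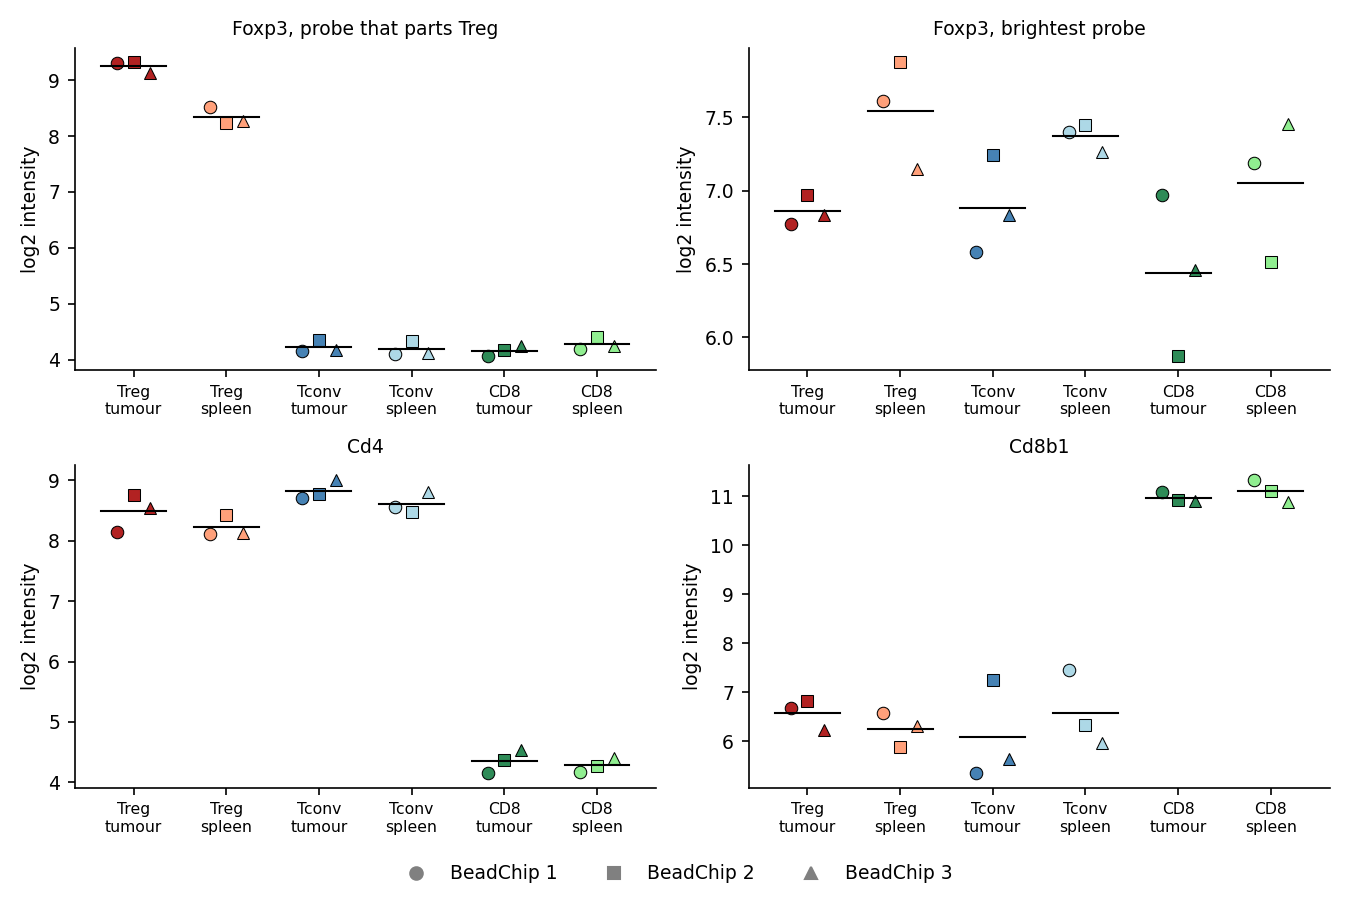
Log2 intensity of 2 Foxp3 probes, Cd4 and Cd8b1 on each of the 18 arrays, by group (symbols, single arrays by BeadChip; bars, group means). The lowest Treg array lies 3.83 above the highest other array on the Foxp3 probe of the first panel, and the brightest Foxp3 probe of the second panel does not part them.

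Tumour Treg against spleen Treg addresses the question of the series, what sets Treg of the melanoma apart. Tumour Treg had higher levels of genes of Treg effector function. Il10, an immunosuppressive cytokine, rose by 2.52 ± 0.18, Havcr2, an inhibitory receptor, by 2.19 ± 0.21, Fgl2, a secreted immunosuppressive protein, by 2.52 ± 0.26, and Prdm1, a transcription factor of effector lymphocytes, by 2.34 ± 0.31. Genes of glucose use rose with them: the lactate exporter gene Slc16a3 by 2.45 ± 0.25, the glucose transporter gene Slc2a1 by 1.65 ± 0.19 and the glycolytic enzyme genes Tpi1 and Aldoa by 2.10 ± 0.24 and 1.38 ± 0.14. Bach2 and Lef1, transcription factors of resting lymphocytes, fell by 2.69 ± 0.38 and 1.39 ± 0.17. Gpr83 and Izumo1r, surface receptors typical of Treg, fell by 2.73 ± 0.50 and 1.72 ± 0.17, and Dtx1, a regulator of Notch signalling, by 2.92 ± 0.31. Dimmer probes of Prdm1, Slc16a3 and Tpi1 did not pass, and Lef1 did not with median scaling in place of quantile normalization (adjusted p = 0.0927).

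Of 22 measured genes of activated and tissue Treg, 12 rose, 0 fell and 10 did not pass, and adjusted over the list alone 18 were higher and 1 lower (camera adjusted p = 6.85e-24; adjusted p = 7.38e-05 with an estimated correlation). The group includes Icos, a costimulatory receptor (1.15 ± 0.18), and Ccr8, a chemokine receptor (1.83 ± 0.26). Of 22 measured glycolysis and hypoxia genes, 14 rose and 0 fell, with a median of 0.99, and adjusted over the list alone 18 were higher (camera adjusted p = 1.70e-27; adjusted p = 1.96e-04 with an estimated correlation). The median was 1.04, 1.27 and 1.24 on the 3 BeadChips. Of 17 measured genes of naive cells and lymphoid homing, 6 fell, among them Igfbp4 (-1.63 ± 0.27) and Ccr7 (-0.91 ± 0.21), and 1, the cytokine receptor gene Il7r, rose (0.70 ± 0.13), with 11 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.57e-10; adjusted p = 0.00160 with an estimated correlation). Of 19 genes of the Treg core list, 4 rose, such as Tnfrsf9 (1.44 ± 0.28) and Ctla4 (0.89 ± 0.18), Gpr83 and Izumo1r fell, and adjusted over the list alone 6 were higher and 2 lower (camera adjusted p = 0.307). In every comparison Foxp3 enters this list on its brightest probe, which does not separate Treg. On the Foxp3 probe that does, tumour Treg lay higher, at 9.30, 9.32 and 9.12, against 8.52, 8.24 and 8.27 in spleen Treg. A dimmer Tnfrsf9 probe gave -0.02, a dimmer Il7r probe did not pass, and with median scaling Igfbp4 and Ccr7 did not (adjusted p = 0.0573 and 0.564). Among 14 chemokine genes 5 rose, with Ccl4 at 4.64 ± 0.56 and Ccl5 at 1.79 ± 0.18, and 9 were higher adjusted over the list alone (adjusted p = 0.0303 with an estimated correlation). Tbx21 and Cxcr3, a transcription factor and a chemokine receptor of type 1 helper cells, rose by 2.15 ± 0.40 and 1.48 ± 0.19.

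Genes of other cell types moved in the same comparison. The largest rises included Clec10a, a lectin of macrophages and dendritic cells (4.46 ± 0.33), Gpnmb, a glycoprotein of pigment cells and macrophages (3.37 ± 0.31), and the macrophage elastase gene Mmp12 (3.14 ± 0.38), beside the transcription factor gene Fosl2 (4.09 ± 0.28). Of 12 melanoma markers 4 rose, with Dct at 1.95 ± 0.46 and Pmel at 2.25 ± 0.54, and the same number adjusted over the list alone. Pmel had an adjusted p of 0.0586 with the replicate block, and the list adjusted p = 0.0649 with an estimated correlation. Dct lay near the floor in spleen Treg, at 4.29, 4.12 and 4.08, so that its difference may be compressed. Of 20 macrophage and monocyte markers, 1, Fcer1g, rose (at least 2.28-fold) and 2 were higher adjusted over the list alone, while the list median was 0.78 (camera adjusted p = 8.77e-06; adjusted p = 0.232 with an estimated correlation). Of 7 erythroid markers 3 fell, with the haemoglobin gene Hba-a1 at -4.90 ± 1.21, and 5 were lower adjusted over the list alone (adjusted p = 0.0945 with an estimated correlation). With the replicate block Lyz1, Lyz2 and Hbb-b1 passed too (adjusted p = 0.00741, 0.00323 and 0.0113), so that 3 macrophage markers rose and 4 erythroid markers fell. Of 7 neutrophil markers 1, Mmp9, rose (2.82 ± 0.32), also adjusted over the list alone (camera adjusted p = 0.0617, and 0.0166 with the replicate block; adjusted p = 0.267 with an estimated correlation), and the dendritic cell gene Zbtb46 was at least 1.91-fold higher. Dimmer probes of Gpnmb, Dct and Pmel did not pass. In all, 356 genes changed, 252 higher and 104 lower, and 355 of them had 1 direction on all 3 BeadChips. The same arrays selected the genes, so that a shared direction, here and below, is no independent check. With median scaling the median of all genes moved by 0.13 and 588 genes were higher and 41 lower. Without spleen Treg replicate 1, 2 or 3 the count was 228, 212 or 235, and without all 6 arrays of replicate number 1, 2 or 3 it was 174, 88 or 121.

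Tconv of tumour and spleen were compared in the same way. Tumour Tconv had higher levels of effector genes: Ifng, the type 1 effector cytokine, rose by 2.00 ± 0.34, the granzyme gene Gzmk by 2.59 ± 0.37, Nkg7, a protein of cytotoxic granules, by 2.80 ± 0.24, and Cxcr3 by 2.33 ± 0.19. Rgs1, a regulator of G protein signalling, rose by 3.34 ± 0.31, and Crem, a cyclic AMP response factor, by 4.38 ± 0.29. Egr3 and Egr2, transcription factors of the early response to the antigen receptor, fell by 2.64 ± 0.37 and 1.51 ± 0.26. Of 6 Crem probes a dimmer one gave -0.23, dimmer probes of Ifng, Egr3 and Tpi1 did not pass, and Egr2 and Gapdh did not with median scaling (adjusted p = 0.242 and 0.0857). Of 17 cytotoxic effector genes 7 rose and none fell, and 8 were higher adjusted over the list alone (camera adjusted p = 5.10e-11; adjusted p = 0.00788 with an estimated correlation). Of 19 Treg core genes 5 rose, among them Ctla4 (1.77 ± 0.18), Tnfrsf18 (1.95 ± 0.21) and Nrp1 (1.52 ± 0.18), and adjusted over the list alone 7 were higher and 1 lower (adjusted p = 0.0110 with an estimated correlation). Of 22 glycolysis and hypoxia genes 4 rose, such as Tpi1 (1.72 ± 0.24) and Gapdh (0.98 ± 0.14), with 12 higher and 1 lower adjusted over the list alone (adjusted p = 0.0114 with an estimated correlation).

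The macrophage genes Clec10a and Lpl were at least 24.9-fold and 13.3-fold higher in tumour Tconv. Of the 20 macrophage markers 2 rose, Fcer1g (1.45 ± 0.28) and Arg1 (1.15 ± 0.26), and 6 were higher adjusted over the list alone, with a list median of 1.09 (camera adjusted p = 1.78e-07; adjusted p = 0.157 with an estimated correlation). Arg1 had a mean of 4.11 in spleen Tconv, near the floor, so that its difference may be compressed. Of the erythroid markers 1, Hbb-b2, fell (-2.83 ± 0.43), and all 7 were lower adjusted over the list alone (adjusted p = 0.0654 with an estimated correlation). Of the melanoma markers 1, Gpnmb, rose (4.59 ± 0.31), also adjusted over the list alone (adjusted p = 0.0841 with an estimated correlation). With the replicate block Lyz1, Lyz2, Hba-a1 and Alas2 passed too (adjusted p = 0.00664, 0.00236, 0.00351 and 0.0248), so that 4 macrophage markers rose and 3 erythroid markers fell. Dimmer probes of Arg1 and Gpnmb did not pass, nor did Arg1 with median scaling (adjusted p = 0.0887). Altogether 173 genes changed, 145 higher and 28 lower, each with 1 direction on all 3 BeadChips, and with median scaling 95 were higher and 3 lower. The count was 106 without tumour Tconv replicate 2 and 99, 36 or 40 without replicate number 1, 2 or 3.

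Tumour CD8 cells carried more transcript of effector genes than spleen CD8 cells. Gzmk rose by 3.27 ± 0.37, Ifng by 2.26 ± 0.34 and Fasl, the ligand of the death receptor Fas, by 1.84 ± 0.26. Genes of the inhibitory and costimulatory receptors Ctla4 (at least 2.88-fold) and Icos (1.32 ± 0.18) rose, as did Nrp1 (2.20 ± 0.18) and Rgs1 (2.24 ± 0.31). Igfbp4 and Il6ra, 2 genes of the naive and lymphoid homing list, fell by 1.32 ± 0.27 and 0.91 ± 0.16. Of 14 chemokine genes 7 rose, also adjusted over the list alone, with Ccl5 at 1.24 ± 0.18, Ccl9 at 3.21 ± 0.37 and Ccl3 at least 2.97-fold higher (camera adjusted p = 5.21e-13; adjusted p = 0.0228 with an estimated correlation). Of 17 cytotoxic effector genes 4 rose, and 6 adjusted over the list alone (adjusted p = 0.0105 with an estimated correlation). Of 17 naive and lymphoid homing genes 3 fell, and 6 adjusted over the list alone (adjusted p = 0.0105 with an estimated correlation). The glycolysis and hypoxia list had 1 gene that rose, Ankrd37 (1.51 ± 0.31), or 2 with the replicate block, and 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.0242 with an estimated correlation). With median scaling Igfbp4, Il6ra and Ankrd37 did not pass (adjusted p = 0.187, 0.145 and 0.0722), and neither did dimmer probes of Rgs1, Igfbp4 and Il6ra.

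Beside these, Gpnmb was at least 19.8-fold and P2ry6, a nucleotide receptor of macrophages, at least 12.6-fold higher in tumour CD8 cells, and Clec10a rose by 4.51 ± 0.33. Of the macrophage markers 3 rose, among them Cd68 (2.21 ± 0.45) and Fcer1g (1.90 ± 0.28), and 9 adjusted over the list alone, with a list median of 1.28 (camera adjusted p = 1.65e-09; adjusted p = 0.105 with an estimated correlation). Hbb-b2 was the 1 erythroid marker that fell (-2.34 ± 0.43), and 5 were lower adjusted over the list alone (adjusted p = 0.179 with an estimated correlation). With the replicate block Lyz1, Lyz2, Tyrobp, Hba-a1 and Hbb-b1 passed too (adjusted p = 0.00202, 8.75e-04, 0.0305, 0.00529 and 0.0422), so that 6 macrophage markers rose and 3 erythroid markers fell. The B cell gene Cd79b fell by 2.06 ± 0.44. With median scaling Hbb-b2 and Cd79b did not pass (adjusted p = 0.0655 and 0.0649), nor did a dimmer Cd79b probe, and a dimmer Gpnmb probe gave -0.07. The test called 170 genes, 128 higher and 42 lower, each with 1 direction on all 3 BeadChips, and with median scaling 95 were higher and 13 lower. A fit to the 6 arrays of this comparison alone called 15, and the fit without replicate number 1, 2 or 3 called 103, 57 or 56.

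**Figure D2:**
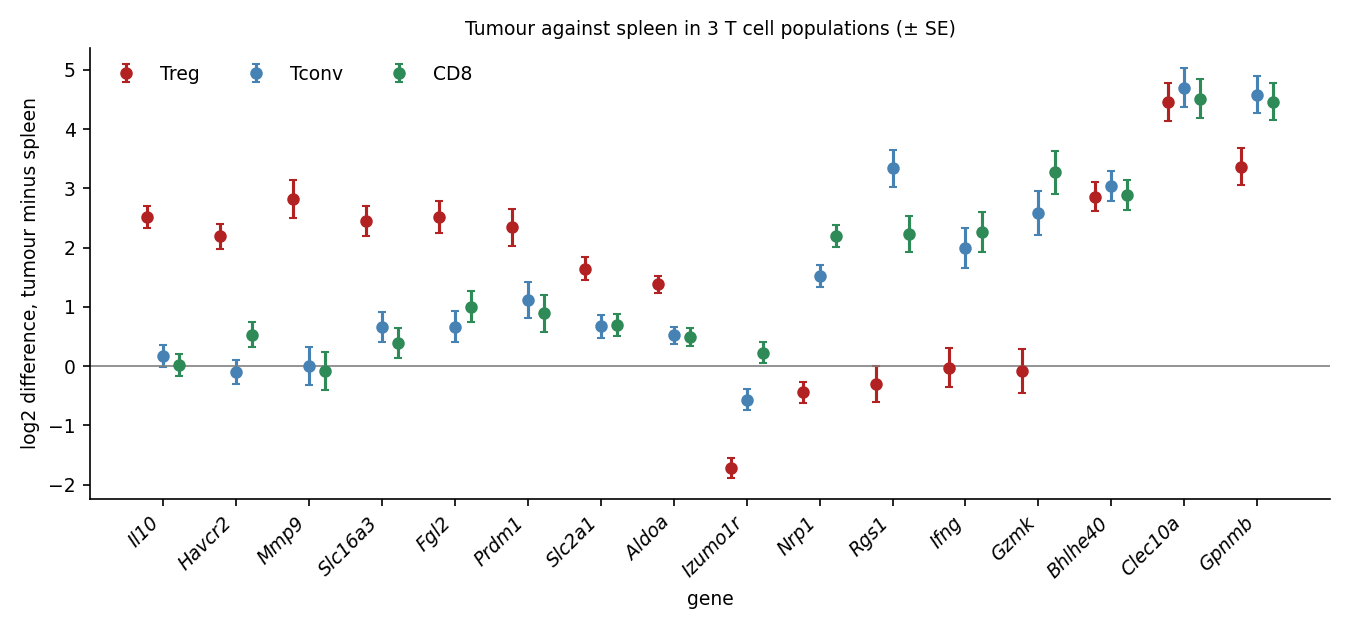
Log2 difference between tumour and spleen in Treg, Tconv and CD8 cells for 16 genes named in the text (points; bars, ± SE; n = 3 arrays in each group). The differences of Il10, Havcr2, Mmp9 and Slc16a3 lie at 2 or more in Treg and below 1 in the other cell types. Those of Nrp1, Rgs1 and Gzmk are larger in Tconv and CD8 cells than in Treg, and those of Clec10a, Gpnmb and Bhlhe40 are high in all 3.

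The 3 tumour against spleen comparisons share no arrays, but the arrays of a replicate number share a BeadChip and the isolated cells were pooled before sorting, which the value for independent lists, here and below, leaves out. Of the genes that rose, 68 were shared by Treg and Tconv, against 2.51 for independent lists, 61 by Treg and CD8 cells, against 2.21, and 68 by Tconv and CD8 cells, against 1.27. In all 3 populations 44 genes rose and 1, Hbb-b2, fell. The shared genes include Bhlhe40, a transcription factor of activated T cells (2.86 ± 0.25 in Treg, 3.04 ± 0.25 in Tconv and 2.89 ± 0.25 in CD8 cells), Tnfaip3, an inhibitor of NF-kappaB signalling (1.23 ± 0.20, 1.87 ± 0.20 and 1.20 ± 0.20), and the heat shock gene Hspa1a (1.11 ± 0.18, 2.37 ± 0.18 and 1.63 ± 0.18). A dimmer Hspa1a probe passed in none of the 3. Clec10a, Gpnmb and Fcer1g, genes known from macrophages, are among them too.

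**Figure D3:**
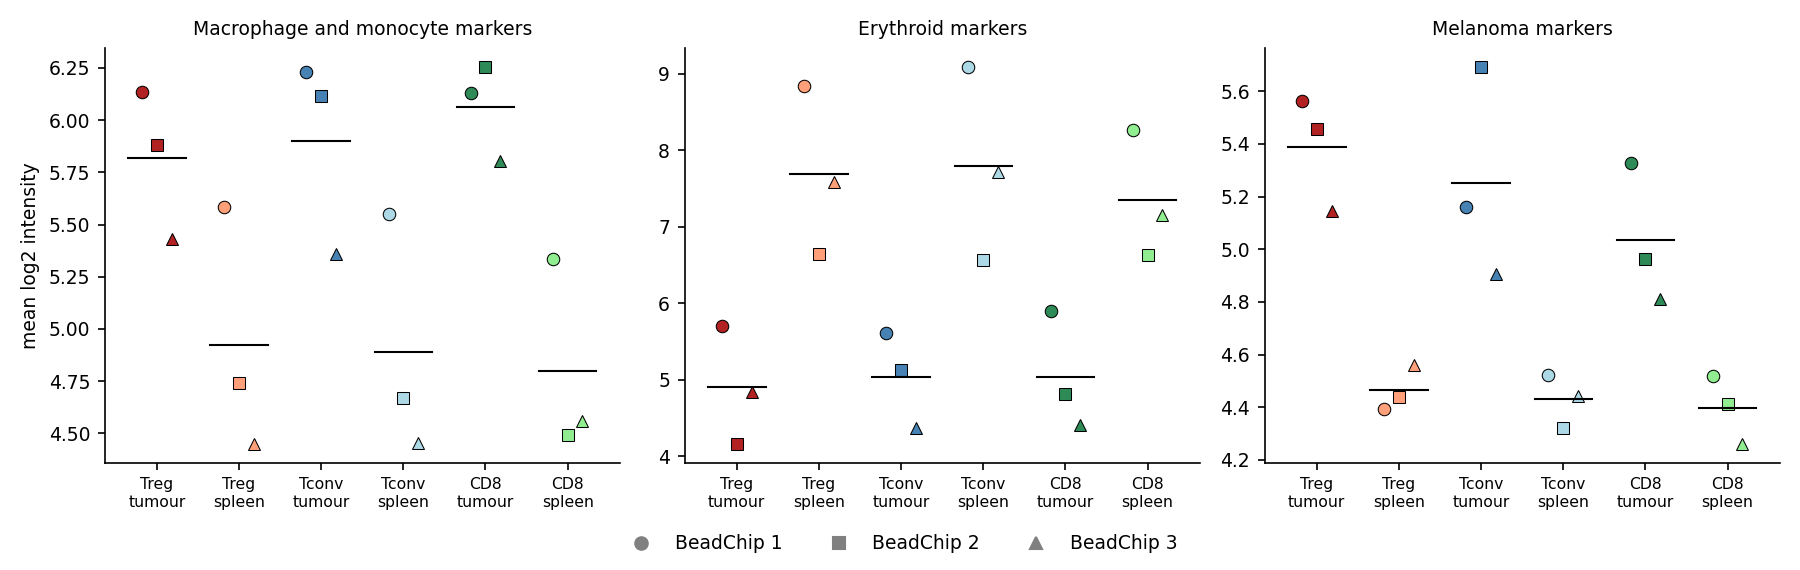
Mean log2 intensity of the measured macrophage and monocyte (20 genes), erythroid (7 genes) and melanoma (12 genes) markers on each of the 18 arrays, by group, with the BeadChip given by the symbol. On each BeadChip the tumour arrays lie higher for macrophage and melanoma markers and lower for erythroid markers, and the arrays of BeadChip 1 lie highest for macrophage markers in the spleen groups.

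Treg were compared with Tconv within each tissue. In the spleen, the Treg genes Ikzf2, a transcription factor, Ctla4, an inhibitory receptor, and Nrp1, a coreceptor, rose by 2.83 ± 0.23, 2.98 ± 0.18 and 3.00 ± 0.18, and Tnfrsf4 by 3.34 ± 0.27. In the tumour, Ikzf2, Ctla4 and Tnfrsf4 rose by 3.39 ± 0.23, 2.10 ± 0.18 and 2.82 ± 0.27, and Klrg1, a receptor of effector lymphocytes, Il10 and Ebi3, a subunit of cytokines made by Treg, rose by 4.04 ± 0.36, 3.36 ± 0.18 and 3.71 ± 0.45. The granzyme gene Gzmk was at least 8.72-fold lower in tumour Treg than in tumour Tconv, and Igfbp4 fell by 3.18 ± 0.27. Of 19 Treg core genes 13 rose in the spleen and 12 in the tumour, with 16 and 15 adjusted over the list alone (adjusted p = 6.16e-06 and 4.43e-05 with an estimated correlation). Of 22 genes of activated and tissue Treg 10 rose in the spleen and 18 in the tumour, with 19 and 21 adjusted over the list alone and medians of 1.08 and 2.30 (adjusted p = 2.10e-05 and 6.16e-06 with an estimated correlation). Of 17 naive and lymphoid homing genes 6 fell in the spleen, such as Dapl1 (-2.87 ± 0.32), and 10 in the tumour, such as Lef1 (-1.73 ± 0.17), with 7 and 13 adjusted over the list alone (adjusted p = 0.00160 and 1.61e-04 with an estimated correlation). Of 22 glycolysis and hypoxia genes 8 rose in tumour Treg, such as Slc16a3 (2.03 ± 0.25; -0.10 on a dimmer probe) and Slc2a3 (1.53 ± 0.21), with 15 adjusted over the list alone (adjusted p = 0.00193 with an estimated correlation), and the list was not called in the spleen (camera adjusted p = 0.502). Of 17 cytotoxic effector genes 3 fell in tumour Treg, Gzmk, Klrd1 (at least 4.14-fold) and Fasl (-1.43 ± 0.26), with 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.00331; adjusted p = 0.157 with an estimated correlation), and the list median of -0.11 turned to 0.04 with median scaling. Macrophage markers had medians of -0.08 in the tumour and 0.04 in the spleen, neither called (camera adjusted p = 0.669 and 0.998), and the first turned to 0.21 with median scaling. Genes of other cell types were higher in tumour Treg than in tumour Tconv: Mmp9 of the neutrophil list by 2.68 ± 0.32 and the dendritic cell gene Zbtb46 at least 1.88-fold, while S100a9, another neutrophil marker, and Cd74, a B cell marker, differed by 1.17 ± 1.11 and 2.45 ± 0.98 and did not pass.

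In the tumour 397 genes changed between Treg and Tconv, 277 higher and 120 lower in Treg, and in the spleen 233, 159 higher and 74 lower, each with 1 direction on all 3 BeadChips. Both tissues shared 73 of the higher genes, against 3.02 for independent lists, and 34 of the lower ones, against 0.609. With median scaling the median of all genes moved by 0.15 in the tumour, and 661 genes were higher and 55 lower there, and 116 and 24 in the spleen. The spleen count was 148 without spleen Treg replicate 2, and without replicate number 1, 2 or 3 the counts were 190, 132 or 133 in the tumour and 135, 64 or 73 in the spleen.

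CD8 cells against Tconv of the same tissue show the genes that part the cytotoxic from the helper lineage. In both tissues CD8 cells had more transcript of Eomes, a transcription factor of cytotoxic cells (2.80 ± 0.24 in the tumour and 2.47 ± 0.24 in the spleen), of the lectin-like receptor gene Klrd1 (3.05 ± 0.25 and 3.06 ± 0.25) and of the chemokine gene Xcl1 (4.05 ± 0.46 and 4.21 ± 0.46). Nkg7 was higher by 1.73 ± 0.24 in the tumour and 4.14 ± 0.24 in the spleen. Maf, a transcription factor of helper cells, fell by 2.28 ± 0.21 in tumour CD8 cells. Itgae, the integrin chain CD103, was higher by 4.52 ± 0.60 in spleen CD8 cells. Dimmer probes of Maf and Itgae did not pass. Of 17 cytotoxic effector genes 6 rose in the tumour and 6 in the spleen, with 8 and 9 adjusted over the list alone (adjusted p = 0.00304 and 0.00551 with an estimated correlation). Of the Treg core genes 3 fell in tumour CD8 cells, Tnfrsf4 (-1.85 ± 0.27), Nrp1 (-1.14 ± 0.18) and Izumo1r (-0.93 ± 0.17), with 2 higher and 6 lower adjusted over the list alone (adjusted p = 0.0388 with an estimated correlation). With median scaling Nrp1 and Izumo1r did not pass (adjusted p = 0.0940 and 0.263). The test called 76 genes in the tumour, 45 higher and 31 lower, and 119 in the spleen, 77 higher and 42 lower, with 25 higher and 12 lower genes in both, against 0.238 and 0.0893 for independent lists. Each had 1 direction on all 3 BeadChips. The spleen count was 76 without spleen Tconv replicate 1, and without replicate number 1, 2 or 3 the counts were 49, 20 or 26 in the tumour and 75, 41 or 34 in the spleen.

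Whether the tumour against spleen difference of Treg differs from that of Tconv or CD8 cells was tested as a difference of differences. Il10 rose more in Treg than in Tconv, by 2.35 ± 0.26, and than in CD8 cells, by 2.50 ± 0.26, and Havcr2 by 2.29 ± 0.30 and 1.66 ± 0.30. The same held for Mmp9, a secreted protease that is also in the neutrophil list (2.81 ± 0.45 and 2.91 ± 0.45), Aldoc, a glycolytic enzyme (1.88 ± 0.22 and 2.09 ± 0.22), and Srxn1, an enzyme of the oxidative stress response (2.52 ± 0.38 and 2.11 ± 0.38). Slc16a3 differed by 2.06 ± 0.36 from CD8 cells, and by 1.78 ± 0.36 from Tconv with an adjusted p of 0.0699, which was 0.0462 with the replicate block. In the other direction, Nrp1 differed by -1.96 ± 0.26 and -2.64 ± 0.26, Rgs1 by -3.63 ± 0.43 and -2.53 ± 0.43, and Tbc1d4, a regulator of glucose transporter traffic, by -3.82 ± 0.67 and -3.79 ± 0.67. Gzmk differed by -3.35 ± 0.52 from CD8 cells, with no probe of it detected in tumour Treg, so that this value rests on the floor there. Dimmer probes of Aldoc, Slc16a3, Rgs1 and Tbc1d4 did not pass. With median scaling Nrp1 did not pass against Tconv (adjusted p = 0.102), nor Rgs1 against CD8 cells (adjusted p = 0.103).

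Of 22 glycolysis and hypoxia genes 0 passed over all genes for Treg against Tconv and 1, Slc16a3, for Treg against CD8 cells, while 9 and 10 were higher adjusted over the list alone. The list medians were 0.63 and 0.70 (camera adjusted p = 1.46e-11 and 7.75e-12; adjusted p = 0.00500 and 0.00474 with an estimated correlation), and both were positive on each BeadChip. Of 22 genes of activated and tissue Treg 2, Il10 and Havcr2, rose more in Treg than in Tconv and than in CD8 cells, with 10 and 8 higher and 1 lower in each adjusted over the list alone (adjusted p = 0.00788 for both with an estimated correlation). The Treg core list had a median of -0.52 against Tconv, with 1 gene lower over all genes and 1 higher and 6 lower adjusted over the list alone (adjusted p = 0.0317 with an estimated correlation), and this median turned to 0.01 with median scaling. Macrophage markers had medians of -0.15 and -0.40 in these differences, neither called (camera adjusted p = 0.674 and 0.152; the first turned to 0.16 with median scaling), and melanoma markers 0.02 and 0.20 (camera adjusted p = 0.795 and 0.322). The detected melanoma markers went both ways, with Dct at 0.95 ± 0.65 and 1.48 ± 0.65, Tyrp1 at 0.58 ± 0.41 and 1.19 ± 0.41, Pmel at 0.62 ± 0.77 and 0.89 ± 0.77 and Gpnmb at -1.22 ± 0.44 and -1.09 ± 0.44, none past the test, and dimmer probes turned the sign of Tyrp1 and Gpnmb in both differences and of Pmel against Tconv. Neutrophil markers had medians of 0.35 and 0.23, called against Tconv but not against CD8 cells (camera adjusted p = 0.0321 and 0.163; adjusted p = 0.209 and 0.400 with an estimated correlation). Mmp9 was the 1 of 7 measured that passed, also adjusted over the list alone, while S100a9 differed by 2.19 ± 1.57 and 1.15 ± 1.57 and Ltf by 1.20 ± 0.69 and 1.09 ± 0.69, neither past the test. Markers of B cells and of dendritic cells were not called in either difference (camera adjusted p = 0.738 and 0.728 for B cells, 0.998 and 0.323 for dendritic cells).

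The tests called 20 genes for Treg against Tconv, 10 in each direction, and 34 for Treg against CD8 cells, 20 higher and 14 lower, with 9 higher and 7 lower genes in both. Both tests use the same 6 Treg arrays, and with no effect simulated lists of these lengths shared 1.37 higher and 1.28 lower genes on average, and independent lists would share 0.0137 and 0.00960. With median scaling the splits were 35 higher and 5 lower, with a median of all genes of 0.13, and 38 and 8, with 0.12. Against Tconv the count was 11, 12 or 9 without spleen Treg replicate 1, 2 or 3, 9 or 11 without tumour Tconv replicate 2 or 3 and 12 without spleen Tconv replicate 3. Against CD8 cells it was 16, 22 or 11 without spleen Treg replicate 1, 2 or 3 and 20 without tumour CD8 replicate 3, and without replicate number 1, 2 or 3 the counts were 4, 0 and 1 against Tconv by limma (846, 757 and 838 at an unadjusted p under 0.05) and 0, 0 and 2 against CD8 cells (1137, 1092 and 1002).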

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

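The tests of the glycolysis genes and of the Foxp3 probes, and the subset of splits that exchange labels equally in both tissues, were chosen only after the results were seen. The test of the macrophage genes with BeadChip means removed was chosen after as well. The other tests of these genes were written before, but without the spleen arrays set beside the tumour arrays.

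A difference between groups singled out 20 genes whose tumour against spleen difference was not the same in Treg and Tconv and 34 for Treg and CD8 cells, by the test of the difference itself. Named among them were Il10 (2.35 against Tconv and 2.50 against CD8 cells), Havcr2 (2.29 and 1.66), Mmp9 (2.81 and 2.91), Aldoc (1.88 and 2.09), Srxn1 (2.52 and 2.11), Nrp1 (-1.96 and -2.64), Rgs1 (-3.63 and -2.53) and Tbc1d4 (-3.82 and -3.79), and against CD8 cells alone Slc16a3 (2.06) and Gzmk (-3.35). Of 100 splits of the arrays, 10 gave as many genes as the 20 against Tconv, the real one included, with 74 in the highest other split, and 8 gave as many as the 34 against CD8 cells, with 130 in the highest other, so that chance is not excluded by this count. Splits that call several times the real number point to a structure of the samples: exchanging more labels in 1 tissue than in the other turns the difference between the cell types themselves into the tested term. Among the splits that exchange equally many labels in both tissues, 1 of 38 and 1 of 43 reached the real number, the real one itself, with 1 and 0 genes in the highest other. Each of these other splits mixes cell types within its groups, which adds their difference to the spread and shrinks the tested term. Low counts there follow largely from this mixing, so that the subset does not exclude chance either.

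The other 7 comparisons allow 10 splits each, too few for a share under 0.05, and in each 1 split, the real one, gave as many genes. The real counts and the highest other were 356 and 3, 173 and 1, and 170 and 3 for tumour against spleen in Treg, Tconv and CD8 cells, 397 and 6, and 233 and 1 for Treg against Tconv in tumour and spleen, and 76 and 0, and 119 and 4 for CD8 cells against Tconv in tumour and spleen. Here too each other split mixes arrays of both groups, which adds their difference to the spread and shrinks the tested term. Low counts there follow largely from this mixing, so that these splits do not exclude chance.

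A signal outside the named genes came from 82 probes without a gene name that passed between tumour and spleen Treg, 40 higher and 42 lower, of 5065 such probes detected, and they were not analysed further here.

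Macrophage and monocyte genes were higher in all 3 tumour populations as a list, a call that was lost with an estimated correlation (adjusted p = 0.232, 0.157 and 0.105), with Lyz1 at 8.37, 8.54 and 8.85 in tumour Treg, Tconv and CD8 cells against 5.70, 5.62 and 5.37 in the spleen, and Tyrobp at 7.48, 7.97 and 8.41 against 6.27, 6.01 and 5.97, neither of which passed alone except, with the replicate block, Lyz1 in all 3 and Tyrobp in CD8 cells. Against the scaling or background correction as the cause, the list's median stayed at the percentile 100 among 1000 matched lists, the lowest over 3 populations and 4 other scalings. Whether RNA of tumour macrophages was carried into the sorted samples stays open. With group means removed the 20 measured genes varied together on the 9 tumour arrays (mean correlation 0.307, percentile 100), which met the rule for carry-over written before. They did so on the 9 spleen arrays too (0.492, percentile 100), a comparison that was not part of that rule. With BeadChip means removed too the tumour arrays lay at the percentile 94, which decides nothing. The spleen arrays then lay at the percentile 30.9 (mean correlation -0.0221). The sort excluded cells with CD11b, whose gene Itgam, like Cd14 and Cybb, lay at the floor, Ctss was detected on all 9 spleen arrays without a rise, and 2 of the 20 genes are in another list as well. No group of cells that carry CD11b was measured, so that a probe at the floor may also be one that does not respond. Expression of such genes by the tumour T cells themselves stays open as well and was not tested.

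Glycolysis and hypoxia genes were higher in tumour Treg than in spleen Treg and more so than in the other tumour populations, and against the brighter tumour Treg arrays as the cause, the median of 0.99 lay at the percentile 100 among 10000 lists matched for expression. The differences from Tconv and CD8 cells had list medians of 0.63 and 0.70, both at the percentile 100, and against RNA of macrophages as the whole cause, their 17 markers detected on at least 3 tumour arrays averaged -0.15 and -0.46, with upper 95% bounds over 3 BeadChips that, less these medians, were -0.29 at most. RNA of melanoma cells stays open: their 10 detected markers averaged 0.12 and 0.32, and an upper bound reached 0.73 above the list's median. This average includes genes near the floor, such as Syngr1 and Ptgds. The pigment cell genes Dct (0.95 and 1.48), Tyrp1, Pmel and Mlana were higher in both differences on the probes used. Gpnmb, a gene of macrophages as well, was lower (-1.22 and -1.09). Dimmer probes turned the sign of Tyrp1 and Gpnmb in both and of Pmel against Tconv. RNA of neutrophils, cells that carry the CD11b excluded by the sort, was not tested and stays open, with list medians of 0.35 and 0.23, called only against Tconv and not with an estimated correlation (adjusted p = 0.209), of 7 measured genes 1, Mmp9, that passed, S100a9 (2.19 and 1.15) and Ltf (1.20 and 1.09, mostly on 1 BeadChip) higher without passing, S100a8 alike in tumour Treg and Tconv and Camp, Csf3r and Mmp8 near the floor. A metabolic difference of Treg in the tumour, a hypothesis found and tested on the same arrays, stays open as well.

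The brightest Foxp3 probe was no higher in Treg than in Tconv. Against mislabelled arrays, the lowest Treg array lay 3.83 above the highest other array on the probe that parts them most. Signal of the brightest probe from RNA other than the Foxp3 message of Treg may explain it: the probe was detected on all 12 other arrays, and the largest gap between its upper and the parting probe's lower 95% bound over both tissues was -3.13, or -3.08 with undetected values of the parting probe, detected on 3 of the 12 other arrays, raised to the lowest detected signal. No biological explanation was tested.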

How the results depend on the processing

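The alternative of the probe with the largest variance was chosen after seeing the data, and the others were set before. Signal over background limits what can be said of dim genes: 38.0 to 45.2 percent of probes lay above background. Of 135 counts under an alternative that keeps all arrays, 110 stayed within 1.5 times the main count, 12 were higher and 13 lower. Of 93 counts without a replicate number or an array, 50 stayed within this limit. Of the values of named genes, 2468 of 2839 kept direction and side of the threshold, 299 no longer passed, 51 newly passed and 21 turned sign. The replicate block moved no count of genes beyond 1.5 times, but over all genes it ended 5 to 26 calls and made 3 to 42 in each comparison, and among the named genes of the text it ended 1 and made 13, given in the report.

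In the order of Treg, Tconv and CD8 cells, tumour against spleen, then Treg against Tconv in tumour and spleen, and CD8 cells against Tconv in tumour and spleen, median scaling gave 629, 98, 108, 716, 140, 48 and 53 genes, and 40 for the difference of differences against Tconv. Array weights gave 643 for Treg and 108 for CD8 cells between tissues, 597 for Treg against Tconv in the tumour, 79 for CD8 cells against Tconv in the spleen and 52 for the difference against Tconv. Every probe counted gave 581, 618, 354 and 33 for Treg between tissues, Treg against Tconv in tumour and spleen and the difference against Tconv. No background correction gave 32 and the authors' values 34 for the last. The cause was not tested. Only the groups of the comparison, with fewer arrays to estimate the spread, gave 69 and 15 for Tconv and CD8 cells between tissues, 185 for Treg against Tconv in the tumour, 27 and 24 for CD8 cells against Tconv in tumour and spleen, and 18 for the difference against CD8 cells. With an estimated correlation 43 of the 86 list tests passed.

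Without 1 replicate number, which leaves 2 arrays in each group, counts ran from 88 to 174, 36 to 99, 56 to 103, 132 to 190, 64 to 135, 20 to 49 and 34 to 75 in the same order, and from 0 to 4 and 0 to 2 for the differences against Tconv and CD8 cells by limma, where 757 genes without number 2, and 1137 and 1092 without 1 and 2, had an unadjusted p under 0.05 where none passed. Without 1 array they ran from 212 to 333, 106 to 139, 117 to 182, 282 to 351, 148 to 187, 56 to 78, 76 to 127, 9 to 29 and 11 to 46. The list tests that passed were 79, 69 and 84 without replicate number 1, 2 and 3.

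Of named genes, a dimmer probe turned the sign of Tnfrsf9 (-0.024, Treg between tissues), Crem and Hspa1a (-0.23 and -0.0042, Tconv), Gpnmb (-0.067, CD8 cells), Slc16a3 (-0.10, Treg against Tconv in the tumour, and -0.27 for the difference against Tconv), Thy1 (-0.055, also the probe with the largest variance) and Cd8b1 (-1.34 in the tumour and -0.75 in the spleen), and, for the differences against Tconv and CD8 cells, of Gpnmb (0.75 and 0.23) and Tyrp1 (-0.088 and -0.16) and, against Tconv alone, of Pmel (-0.38). Foxp3 in tumour Treg against Tconv, -0.02 on the brightest probe, turned to 0.47 with median scaling, 1.14 with the mean of all probes, 0.0397 with array weights, -0.13 to 0.10 without 1 replicate number and 5.01 on the parting probe, the one with the largest variance, against Tconv values near the background. Where another probe gave the value, the change of probe is the cause, and otherwise the cause was not tested.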

Other observations

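The simulation of genes shared by both differences of differences was chosen only after the result was seen, and the other values here carry no test of their own.

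Both differences of differences called the same 16 genes. Il10, Havcr2, Mmp9, Aldoc and Srxn1 were among the 9 with the higher difference in Treg, and Nrp1, Rgs1 and Tbc1d4 among the 7 with the lower. The shared counts of 9 and 7 compare with at most 4 in each direction in 100 simulated data sets without any effect, in which the tests also shared the 6 Treg arrays. Genes were simulated as independent of each other. A gene that changes between tissues in Treg alone enters both differences alike. Counts above a simulation without any effect are therefore no separate evidence for the 16 genes.

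Macrophage and erythroid markers also differed between BeadChips. In the spleen groups the mean of Lyz1 was 7.33, 5.04 and 4.33 on BeadChips 1, 2 and 3, and in the tumour groups 9.19, 8.65 and 7.92.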
